A study of Mus musculus with 12 samples.

How the data were processed

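RNA was measured in 12 libraries of mouse islets or islet cells, 3 in each of 4 groups: whole islets with no doxycycline (Dox), whole islets after 1 week of Dox, sorted CD11b-positive macrophages and sorted CD31-positive endothelial cells, the sorted cells from dispersed islets after 1 week of Dox. Per the labels' protocols, RNA from islets or sorted cells was isolated with RNAqueous kits, amplified with a NuGEN Ovation kit, sheared and made into libraries with a NEBNext DNA kit, and sequenced on an Illumina HiSeq2500. The labels do not state whether libraries of a group came from separate animals, so p-values measure the spread between samples.

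The signal values were normalized by the authors before they were deposited, by a method not given in the sources used here. TopHat2 2.0 and build mm9 are named in the submitters' processing notes, without their roles. Counting program, use of strand and annotation release are not given in the sources used here. The values are linear, with a floor of 1 in every library. Above the floor they lie on whole multiples of a step specific to each library (99.9 to 100% of low values, within a tolerance of 0.1 step), and 45.5 to 60.05% of low values were multiples of 50 steps. Whole reads could therefore not be recovered, and no count model was used. Were 50 steps 1 read, the libraries would hold 7.47 to 35.4 M reads.

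The table held 22793 genes by Ensembl ID. The 25 symbols stored as dates were restored through the IDs, and for 76 symbols with several entries the entry with the highest mean was used, which left 22711. The coordinates of 22382 of 22742 IDs found in GENCODE M1, an annotation of the same build, were the same.

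Values were analysed as log2 of (signal + 1), as deposited, with limma 3.58.1 in R 4.3.3. Each comparison was a linear model of its 6 libraries with a variance trend in the empirical Bayes step, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes of genes near the floor are understated by the added 1. Before the data were examined, the filter was set to a value of at least 1 in at least 3 libraries, or the 40th percentile of non-zero values if 1 is not a low level. Because 1 is the floor, the literal filter removes nothing. The 40th percentile, 15.5, was used instead, in at least 3 of the 6 libraries. This choice decides much of the islet result: 829 genes passed with it and 97 with no filter, 81 of them shared.

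The 29 gene lists, the tests and the rule for naming genes were set before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Camera compares a list with the other genes and fry asks whether the list itself changed, so their calls answer different questions. The rule named Vegfa, the 8 largest rises and 8 largest falls per comparison among genes past the threshold with no overlap of groups and a mean of at least 716 (the 75th percentile of non-zero values), and 2 to 4 members of each list. In islets, 93 of the 95 genes of the rule are named, and the other 2 are not reported here. In the comparisons of sorted cells, 65 of 115 (macrophages against endothelial cells), 81 of 119 (macrophages against islets) and 75 of 121 (endothelial cells against islets) are not named, and which lists to describe there was decided after values were seen. Of these unnamed genes, 10, 6 and 5 changed sign under an alternative in which they were tested, of which 0 had passed the threshold. Outside the rule, after their values were seen, mainly to complete counts of 5 or fewer, the text also names Kdr, Cspg4, Myh11, Mertk, Mpeg1, Ctgf, Pdgfa, Itga6 and Itgb1 in islets. Between the fractions these are Vegfb, Fn1, Cxcr4, Plaur, Nos2, Clec9a, Zbtb46, Cx3cl1, Cxcl12 and Il34, in macrophages against islets Nos2, Arg1, Clec9a and Zbtb46, and in endothelial cells against islets Vegfb, Il10, Stab1, Nos2, Clec9a, Zbtb46, Dusp1 and Jun.

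Deviations of same-numbered libraries from their group means, over genes, correlated at 0.20, 0.36 and 0.31 between macrophages and endothelial cells. Here 6 of 6 libraries were closest to their own number. With 3 libraries per group such a match can arise by chance, and the labels do not state pairing. Pairing of these libraries was therefore possible but not established. The main fit between the fractions had no replicate block, so its p-values ignore any pairing. Pairing entered the tests of genes and lists only as an alternative. The association of the islet response with the fractions was tested with a two-sided Fisher's exact test. Permutation tests compared lists over genes, with 10000 or 1e+05 permutations.

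On simulated values with 200 changed genes per comparison, the test recovered 22.2% of genes changed by 2 on the log2 scale in islets, 64.3% between the fractions, 50.0% between macrophages and islets and 58.8% between endothelial cells and islets. At a log2 change of 1 it recovered 0, 28.6, 6.12 and 9.28%. Fewer genes changed in the simulation than were called in each comparison, and its noise was independent between genes. Recovery in the data may therefore differ. Alternatives covered the pseudocount, filter, scaling, variance trend, 4 groups in one fit, a replicate block, a minimum fold, duplicate symbols, and each library left out. Removal of the GC trend, omission of 2 libraries that stand apart, voom weights, a covariate for the series of library numbers, an estimated correlation with a replicate block and the odds ratio with 1 library left out were added after the data were seen. Alternatives that need counts were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6.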

Results

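RNA was sequenced from whole islets and from islet cells of RIP-rtTA; TetO-VEGF-A mice, in which doxycycline (Dox) switches on a VEGF-A transgene in beta cells. The 12 libraries fell into 4 groups of 3, namely whole islets without Dox, whole islets after 1 week of Dox, CD11b-sorted islet macrophages after 1 week of Dox and CD31-sorted islet endothelial cells after 1 week of Dox. Both sorted fractions came from dispersed purified islets. The unit throughout was the authors' normalized expression signal, a linear value whose floor was 1, and means are given with the standard deviation of 3 libraries (SD, n = 3). The summed signal per library ran from 17635776 to 25226447. Numbers of sequenced reads are not given in the sources used here, so no counting interval was attached to a value. In a principal component analysis, the component with 48.9% of the variance parted macrophages from the other groups, and the next, with 33.1%, parted endothelial cells.

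Vegfa, the gene of the growth factor carried by the transgene, was not higher in Dox islets. Its signal was 3967 ± 637 (SD, n = 3) without Dox and 2028 ± 422 (SD, n = 3) after 1 week of Dox, a log2 difference of -0.98 (SE 0.30) with limma's adjusted p = 0.0853. Over the alternatives with no minimum fold, the adjusted p ran from 0.0275 to 0.267, and Vegfa was called lower when each library's GC trend was removed (0.0275) and when the 4 groups were fitted together (0.0359). The gene is listed as ENSMUSG00000023951 on chromosome 17 from 46153942 to 46169326 of build mm9. Macrophages held 216 ± 5.04 (SD, n = 3) and endothelial cells 59.8 ± 15.5 (SD, n = 3). Induction of the transgene could not be checked from this value, because its sequence, and how much of it the authors' gene model would count, are not given in the sources used here.

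**Figure D1:**
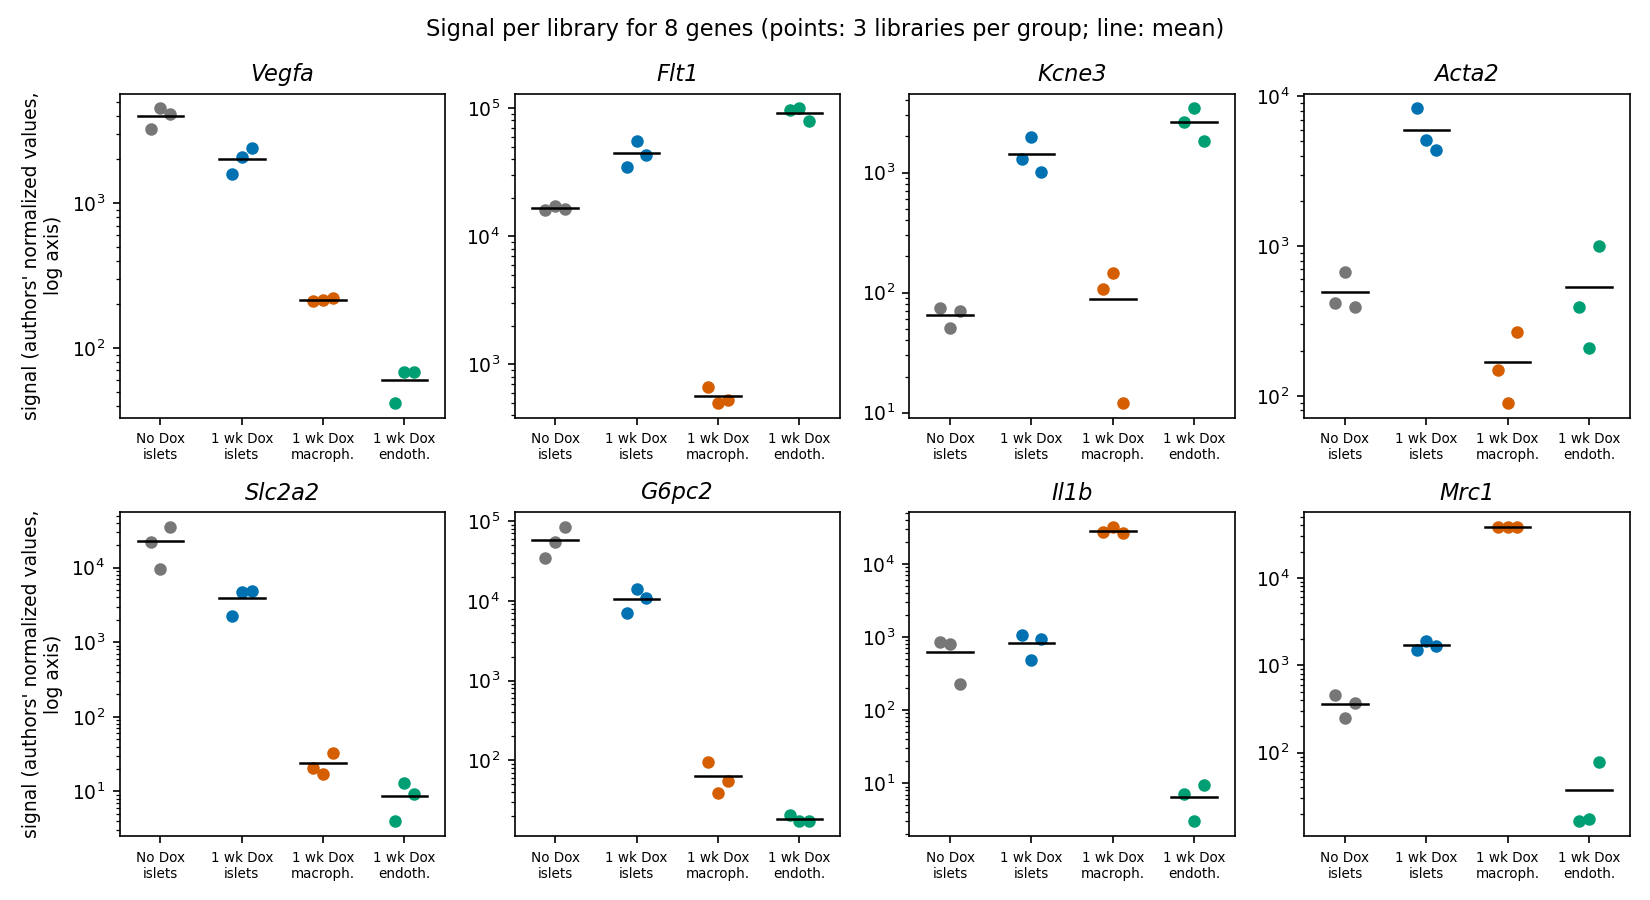
Signal per library (authors' normalized values, log axis) of 8 genes in whole islets without Dox, whole islets after 1 week of Dox, and sorted macrophages and endothelial cells after 1 week of Dox. Points are the 3 libraries of a group and lines their means; Slc2a2 averaged 22460 without Dox and 3969 with Dox, and Il1b averaged 28471 in macrophages and 6.52 in endothelial cells.

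The comparison of whole islets with and without Dox asks which transcripts differ after 1 week of Dox. Part of the genes of vessels, matrix and dividing cells rose and part of those of beta cells fell. All 18 acinar genes also lay above 0, with a median log2 change of 1.44, though 0 passed the threshold. With an estimated correlation, 0 of the 29 gene lists were called. Among genes with a mean of at least 716 in either group, past the threshold and with no overlap of groups, the largest named rise was that of Kcne3, a potassium channel subunit of the angiogenesis list, from 65.2 ± 12.4 to 1425 ± 489 (SD, n = 3), a log2 change of 4.39 (SE 0.41, adjusted p = 0.00590). It was followed among these by Fn1, which encodes fibronectin, with a log2 change of 3.62 (SE 0.34, adjusted p = 0.00590), and Acta2, smooth muscle actin, with 3.57 (SE 0.35, adjusted p = 0.00674). The other 5 of these rises were Frem2 (3.51), Tnfsf18 (3.46), Myocd (3.38), Prnd (3.36) and Adam12 (3.21). Among the falls, G6pc2, the islet glucose-6-phosphatase, went from 57859 ± 25529 to 10684 ± 3581 (SD, n = 3), a log2 change of -2.40 (SE 0.43, adjusted p = 0.0171), and Slc2a2, the glucose transporter of beta cells, had a log2 change of -2.39 (SE 0.50, adjusted p = 0.0281). The other falls named on these terms were Itgad (-4.55), Grm3 (-2.96), C7 (-2.65), Vdr (-2.40), Ky (-2.37) and Ccdc162 (-2.35). In each of these 16 genes the 3 libraries of one group lay above all 3 of the other. Kcne3 is ENSMUSG00000035165 on chromosome 7 from 107327207 to 107333374, and G6pc2 is ENSMUSG00000005232 on chromosome 2 from 69049130 to 69065898. In all, 829 of 14443 genes tested with limma passed an adjusted p of 0.05, of which 625 were higher and 204 lower with Dox. Further, 25.4% of the tested genes had non-overlapping groups, against 10% by chance. Here and below, the 10% is an average over all splits of libraries that do not differ by group. Genes vary together, so the share of a single split can lie far from it. The count depended on the filter and on individual libraries. With no filter on low values, which is the literal reading of the rule set before the data were examined, 97 genes passed, 81 of them among the 829. Only 5 passed without Dox replicate 2, 88 without Dox replicate 3 and 456 without No Dox replicate 1. Of the 62 named islet genes that passed, 55 no longer did without Dox replicate 2 and 54 with no filter; Acta2, Fn1, Kcne3 and Prnd passed under every alternative run. Of the 40 named islet genes that had not passed, 20 were called under at least 1 alternative. The share of called genes that were higher, 75.4%, was 59.96% after quantile normalization, 64.1% after median ratio rescaling and 59.1% of 1679 genes after removing each library's GC trend. The median log2 change of all tested genes was 0.11 as deposited and -0.04, -0.01 and -0.02 in those fits.

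Endothelial and angiogenic genes were higher in Dox islets. In the endothelial list, 7 of 18 tested members rose (16 adjusted over the list alone), among them the tight junction gene Cldn5 from 4.52 ± 1.58 to 78.7 ± 31.7 (SD, n = 3), the fenestral diaphragm gene Plvap (log2 change 1.88) and Cdh5, which encodes VE-cadherin (1.85), while Ptprb stood at 1.04 (adjusted p = 0.126). In the list of tip cell and angiogenesis genes, 9 of 16 rose (13 adjusted over the list alone), with Kcne3, the apelin receptor gene Aplnr (2.72) and the basement membrane gene Nid2 (2.57) as the largest, and Trp53i11 at 1.69 (adjusted p = 0.0577). Among VEGF ligands and receptors, 4 of 10 rose, namely the receptor genes Nrp2 (1.67), Flt4, Flt1 (1.40) and Kdr (1.22). Adjusted over the list alone, 5 rose and Vegfa fell, and Nrp1 stood at 1.16 (adjusted p = 0.0850). Flt1, the gene of VEGF receptor 1, averaged 16543 ± 662 without Dox and 44367 ± 10309 with Dox (SD, n = 3). The camera test with a preset correlation placed the endothelial, angiogenesis and VEGF lists above other genes with adjusted p = 2.41e-09, 7.80e-13 and 0.0401. With an estimated correlation the adjusted p was 0.0629, 0.0629 and 0.194.

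Mural cell, fibroblast and matrix genes were higher as well. In the pericyte and smooth muscle list, 5 of 12 members rose (9 adjusted over the list alone), namely Acta2, Tagln (2.04), Higd1b (2.00), Myh11 (1.99) and Cspg4 (1.99), while the pericyte marker Rgs5 averaged 86914 ± 41588 without and 290190 ± 115690 with Dox (SD, n = 3; adjusted p = 0.111). In the list of fibroblast and interstitial collagen genes, 7 of 12 rose (8 adjusted over the list alone), led by Postn, or periostin (2.70), and the collagen genes Col5a1 (2.24) and Col1a2 (2.21); Col3a1 stood at 1.64 (adjusted p = 0.138). In the basement membrane list, 10 of 13 rose (13 adjusted over the list alone), including Fn1, Col18a1 (3.00) and Col4a1 (2.59), with Hspg2, the perlecan gene, at 1.47 (adjusted p = 0.222). Among matrix proteases and inhibitors, 6 of 16 rose (13 adjusted over the list alone), with the metalloproteinase genes Mmp13 (from 37.8 ± 27.5 to 328 ± 133, SD, n = 3) and Mmp14 (2.84) and with Adamts4 (2.58) the largest, and Timp3 stood at 1.15 (adjusted p = 0.149). Among integrins, 5 of 16 rose (9 adjusted over the list alone), namely Itga5 (2.56), Itgb3 (2.30), Itga9 (1.86), Itgb1 (1.68) and Itga6 (1.68), and Itga1 stood at 1.56 (adjusted p = 0.0604). For these 5 lists, camera's adjusted p was 1.63e-06, 1.30e-05, 3.36e-13, 2.41e-09 and 2.34e-06 with the preset correlation, and 0.0629, 0.156, 0.0940, 0.112 and 0.105 with an estimated correlation.

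Macrophage markers were higher in Dox islets. In the macrophage list, 5 of 17 members rose (13 adjusted over the list alone), namely Emr1 (2.12), Aif1 (1.88), the fractalkine receptor gene Cx3cr1 (1.74), Mpeg1 (1.73) and Mertk (1.38), and lysozyme gene Lyz2 stood at 1.83 (adjusted p = 0.0509). In the list of alternatively activated macrophages, 3 of 9 rose (3 adjusted over the list alone, with 1 lower), namely the scavenger and mannose receptor genes Stab1 (2.28), Mrc1 (2.27) and Cd163 (2.07), with Il4ra at 0.61 (adjusted p = 0.292). In the proinflammatory list, 0 of 13 passed limma's adjusted test (2 adjusted over the list alone, 4 at an unadjusted p under 0.05), though all 13 lay above 0 with a median of 1.04; Il1b averaged 629 ± 350 without and 836 ± 308 with Dox, and Cd86 610 ± 455 and 731 ± 115 (SD, n = 3). Among chemokines and myeloid growth factors, the monocyte attractants Ccl7 (3.25) and Ccl9 (2.06) rose out of 15 tested (8 adjusted over the list alone). Among growth factors, 5 of 22 rose (9 adjusted over the list alone, with 1 lower), namely Tgfb3 (2.61), Igf1 (2.46), Nov (1.84), Ctgf (1.65) and Pdgfa (1.33), with Fgf1 at 0.85 (adjusted p = 0.206). Of 10 dendritic cell genes and 8 genes of T, NK and B cells, 0 passed, with 3 higher in each when adjusted over the list alone and 3 in each at an unadjusted p under 0.05. Zbtb46 stood at 1.19 (adjusted p = 0.0516), Clec9a at 1.24 (adjusted p = 0.113), Cd4 at 2.81 (adjusted p = 0.0595) and Trac at 2.42 (adjusted p = 0.0764). Of 3 neutrophil genes tested 0 passed, and 0 had an unadjusted p under 0.05; Elane and Csf3r stood at 0.54 and 0.65 (adjusted p = 0.783 and 0.716). With the preset correlation, camera's adjusted p was 4.28e-09 for macrophages, 0.0128 for alternatively activated, 0.0128 for proinflammatory, 0.000115 for chemokines, 0.000500 for growth factors, 0.0268 for dendritic cells, 0.0153 for T, NK and B cells and 0.914 for neutrophils. With an estimated correlation these adjusted p were 0.102, 0.152, 0.246, 0.168, 0.172, 0.172, 0.145 and 0.919.

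Beta cell genes were lower in Dox islets and genes of the cell cycle were higher. All 20 members of the list of beta cell identity and secretion lay below 0, and 10 fell (18 adjusted over the list alone), with G6pc2, Slc2a2 and the zinc transporter gene Slc30a8 (-1.98) the largest; Iapp, which encodes islet amyloid polypeptide, averaged 165730 ± 59565 without and 78606 ± 20561 with Dox (SD, n = 3; adjusted p = 0.256). Summed over the list, beta cell genes held 2.60 to 4.01% of the signal in the No Dox libraries and 1.11 to 1.18% in the Dox libraries. Of 11 tested genes of the other islet endocrine cells 0 passed, and 4 had an unadjusted p under 0.05; glucagon gene Gcg stood at -0.89 (adjusted p = 0.409) and Ttr at -1.35 (adjusted p = 0.0705). Among genes of immature beta cells or normally shut off in them, Ldha, the lactate dehydrogenase A gene, rose (2.21) out of 10, and Cd81 stood at 1.09 (adjusted p = 0.121). Of the cell cycle list, 11 of 20 rose (16 adjusted over the list alone), with the mitotic genes Ccnb1 (3.71), Bub1 (3.56) and Cdk1 (3.38) the largest, and Mki67 averaged 1736 ± 1250 without and 9826 ± 6418 with Dox (SD, n = 3; adjusted p = 0.0607). By camera, the adjusted p was 6.58e-17 for beta cells, 0.0559 for other endocrine cells, 0.0420 for immature beta cells and 3.12e-10 for the cell cycle with the preset correlation, and 0.0694, 0.380, 0.168 and 0.145 with an estimated correlation.

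Few genes of the remaining lists passed the test in islets. Of 13 unfolded protein response genes 0 passed (3 at an unadjusted p under 0.05). Their median log2 change was -0.48, with Hsp90b1 at -0.50 (adjusted p = 0.722) and Hspa5 at -0.45 (adjusted p = 0.586). In the hypoxia list, Ldha rose out of 13 and Ndrg1 stood at -0.23 (adjusted p = 0.742). In the list of p53 and apoptosis, 1 of 14 genes rose and Ccng1 stood at -0.11 (adjusted p = 0.944). Of 13 interferon response genes 0 passed (4 adjusted over the list alone, 5 at an unadjusted p under 0.05), with B2m at 1.09 (adjusted p = 0.375), and of 13 immediate early genes 0 passed (2 at an unadjusted p under 0.05), with Egr1 at -0.38 (adjusted p = 0.630) and Fos at 0.05 (adjusted p = 0.970). Of 10 ductal, 7 Schwann cell and 6 red blood cell genes tested, 0 passed limma's adjusted test, and 3, 3 and 0 had an unadjusted p under 0.05. Adjusted over the list alone, 2 ductal genes were lower, and of the Schwann cell genes 1 was higher and 1 lower. Clu averaged 1513 ± 513 without and 2123 ± 150.4 with Dox (SD, n = 3). Spp1 stood at 0.45 (adjusted p = 0.661), Mbp at -1.19 (adjusted p = 0.103), Cdh19 at -0.47 (adjusted p = 0.761), Hbb-b1 at -0.20 (adjusted p = 0.924) and Hbb-b2 at -0.71 (adjusted p = 0.705). Camera's adjusted p with the preset correlation was 0.00339 for the unfolded protein response (lower), 0.669 for hypoxia, 0.0547 for p53 and apoptosis, 0.0153 for the interferon response (higher), 0.708 for immediate early genes, 0.614 for ductal, 0.669 for Schwann and 0.775 for red blood cells. With an estimated correlation these adjusted p were 0.105, 0.705, 0.172, 0.246, 0.866, 0.684, 0.844 and 0.914. The medians of the ductal (0.50), Schwann (0.01) and neutrophil (0.54) lists lay above 0 although camera placed these lists below other genes. All 18 acinar genes, which mark exocrine tissue carried with islets, lay above 0 with a median of 1.44, and 0 passed limma's adjusted test (12 at an unadjusted p under 0.05). Cpb1 averaged 21285 ± 7524 without and 56815 ± 37481 with Dox, and Ctrb1 19061 ± 20050 and 38600 ± 17533 (SD, n = 3). Camera's adjusted p for them was 6.67e-06, and 0.291 with an estimated correlation. Acinar genes held 0.229 to 0.760% of the signal in No Dox and 0.549 to 1.82% in Dox libraries. Across genes, the deviation of a library from the mean of its group had a Spearman correlation with GC content of 0.64 in No Dox replicate 2 and 0.57 in Dox replicate 1, against -0.33 to -0.44 in the other 4 islet libraries; genes are not independent replicates. Without these 2 libraries, 301 genes passed in islets, of which 274 were among the 829.

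**Figure D2:**
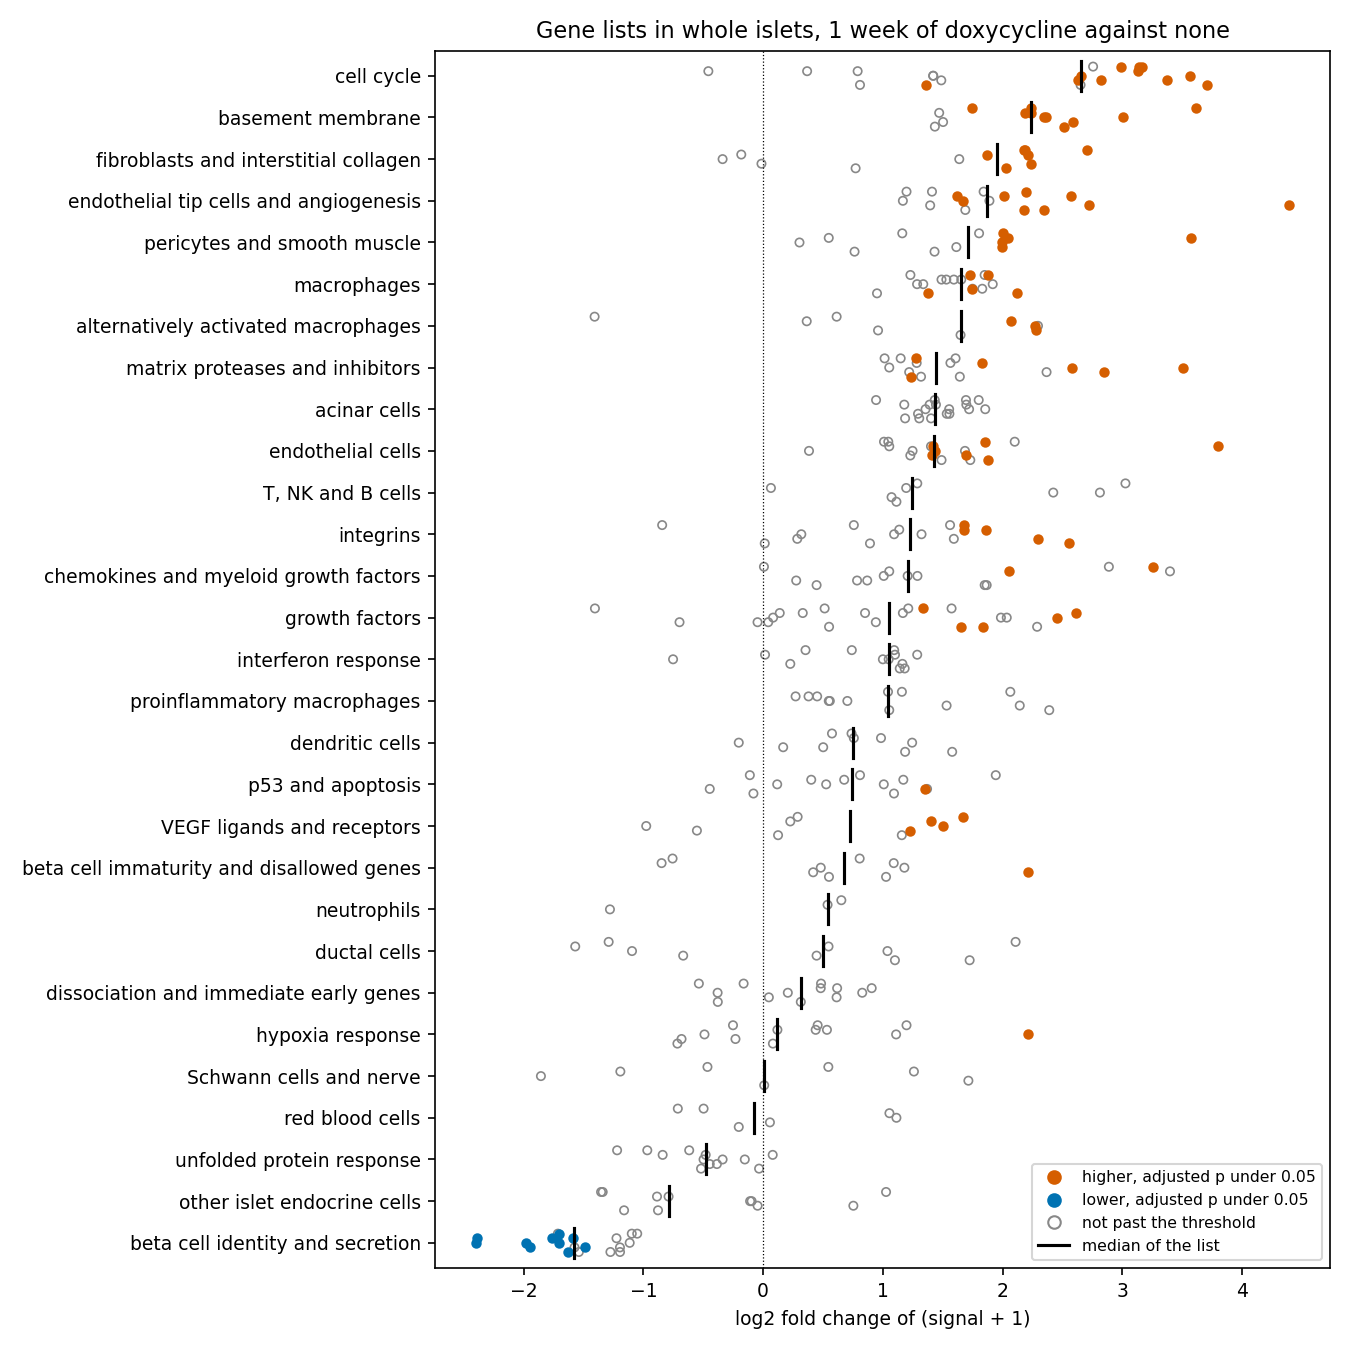
Log2 fold change of (signal + 1) in whole islets, 1 week of Dox against none (3 against 3 libraries), for each tested member of the 29 gene lists, ordered by list median (vertical line). Filled points passed limma's adjusted p of 0.05 (higher to the right, lower to the left of 0) and open points did not; 11 of 20 cell cycle genes passed as higher and 10 of 20 beta cell genes as lower.

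The comparison of sorted macrophages with sorted endothelial cells asks which transcripts part these cell types after 1 week of Dox. Each fraction carried the genes of its own type at levels far above those of the other. Among genes chosen on the same terms, the largest differences on the macrophage side were as follows. Ccl4, a chemokine gene, averaged 27298 ± 2272 in macrophages and 5.39 ± 4.07 in endothelial cells (SD, n = 3; log2 difference 12.34, SE 0.54, adjusted p = 4.67e-07), and the cytokine gene Il1b 28471 ± 3248 and 6.52 ± 3.24 (SD, n = 3; 11.99, SE 0.34, adjusted p = 7.32e-08). Ms4a7, Tyrobp, Cybb, Clec4n, Mmp12 and Tnf followed with log2 differences from 11.94 to 11.57. On the endothelial side, Enpp6 averaged 7.21 ± 8.09 in macrophages and 2749 ± 180 in endothelial cells (SD, n = 3; log2 difference -8.92, SE 0.70, adjusted p = 1.23e-05), and Arhgef15, Kcnj15, Lhx6, Lpar4, Unc45b, Clec14a and Sema3g ran from -8.89 to -8.46. Il1b is ENSMUSG00000027398 on chromosome 2 from 129190306 to 129196875, and Enpp6 is ENSMUSG00000038173 on chromosome 8 from 48072279 to 48180249. In all, 8117 of 13726 tested genes passed limma's adjusted p of 0.05, 3798 higher in macrophages and 4319 higher in endothelial cells, of which 2809 and 2888 differed by at least 2-fold; 66.5% of genes had non-overlapping groups, against 10% by chance.

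The macrophage fraction held both sets of macrophage activation genes. Itgam, which encodes the CD11b used for sorting, averaged 11422 ± 33.4 in macrophages and 7.34 ± 5.20 in endothelial cells (SD, n = 3). All 17 macrophage markers were higher in macrophages, with Tyrobp, C1qb (11.50) and the chemokine receptor gene Ccr2 (11.17) the largest, as were 12 of 13 genes of alternatively activated and 12 of 13 of proinflammatory macrophages (the same counts adjusted over each list alone). Mrc1 averaged 38380 ± 256 in macrophages and 37.0 in endothelial cells, and Cd86 66369 ± 11506 and 42.4 ± 25.4 (SD, n = 3). The lectin genes Mgl2 and Clec10a averaged 1228 ± 244 and 1179 ± 357 in macrophages (SD, n = 3) and were listed at the floor of 1 in all 3 endothelial libraries; as near copies of each other, their reads cannot always be told apart. Arg1, an arginase used as a marker of alternative activation, stood at 0.69 (adjusted p = 0.0827; 0.0353 with a replicate block and 0.0459 without macrophage replicate 2), and Nos2, the inducible nitric oxide synthase gene of the proinflammatory list, was the exception in being higher in endothelial cells. Its mean was 37.0 ± 17.2 in macrophages and 1329 ± 38.4 in endothelial cells (SD, n = 3). Of the neutrophil list 9 of 11 were higher in macrophages, with Csf3r at 9.59, and of the dendritic cell list 8 of 10, with Itgax (10.57) and Cd209a (10.50) the largest, while Zbtb46 (-2.06) and Clec9a (-2.33) were higher in endothelial cells. Of the chemokine list 12 of 16 were higher in macrophages and Cxcl12 (-4.79), Cx3cl1 (-3.49) and Il34 (-2.09) in endothelial cells. Immediate early genes were also higher in macrophages, 12 of 13 (13 adjusted over the list alone), with Ier2 (2.82), Zfp36 (2.50) and Egr1 (2.17) among them. For macrophage markers, camera's adjusted p was 1.19e-10, and it was 5.19e-06 for alternatively activated, 1.51e-06 for proinflammatory, 0.000267 for neutrophils, 0.00394 for dendritic cells, 8.41e-05 for chemokines and 5.08e-06 for immediate early genes. With an estimated correlation these adjusted p were 0.127, 0.127, 0.0941, 0.127, 0.127, 0.124 and 0.0941.

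The endothelial fraction held the vessel, angiogenesis and basement membrane genes. All 18 endothelial markers were higher in it, with Emcn, which encodes endomucin, averaging 215 ± 98.0 in macrophages and 59212 ± 4847 in endothelial cells (SD, n = 3), followed by Ptprb (-8.03) and Plvap (-7.80). So were 14 of 16 tip cell and angiogenesis genes, the exceptions being Plaur (3.25) and Cxcr4 (0.86), and 12 of 13 basement membrane genes, with Hspg2 (-7.56), Lama4 (-6.94) and Lama5 (-6.79) named and Fn1 (1.94) the exception. The VEGF receptor genes Kdr (-7.48), Flt4 (-7.38) and Flt1 (-7.36) were higher in endothelial cells and the ligand genes Vegfa (1.87) and Vegfb (1.96) in macrophages, 7 and 2 of 9 tested. Among growth factors, 11 of 20 were higher in endothelial cells, including Nov (-8.00) and Fgf1 (-7.71), and 5 in macrophages, including Areg, which averaged 183 ± 27.2 in macrophages (SD, n = 3) and was listed at the floor of 1 in the endothelial libraries. Igf1, the insulin-like growth factor gene, averaged 8984 ± 193 in macrophages and 9167 ± 1408 in endothelial cells (SD, n = 3; log2 difference -0.02, adjusted p = 0.915). Endothelial markers had a camera adjusted p of 1.19e-10, followed by 1.36e-05 for angiogenesis, 1.49e-06 for basement membrane, 0.00378 for VEGF genes and 0.112 for growth factors, and with an estimated correlation 0.127, 0.127, 0.252, 0.158 and 0.338.

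Transcripts of other islet cells were present in both fractions, those of beta cells at low levels and those of acinar cells at levels that differed widely between replicates. As a share of the Dox islet mean, Ins1 stood at 3.56% ± 2.24 in macrophages and 0.446% ± 0.214 in endothelial cells, Ins2 at 3.26% ± 1.39 and 0.379% ± 0.0395, and the median beta cell gene at 1.90% ± 0.792 and 0.279% ± 0.0420 (SD, n = 3). Of the beta cell list, 13 of 15 tested members were higher in macrophages than in endothelial cells, with Pcsk2 (3.88) and Glp1r (3.75) the largest (camera adjusted p = 0.00125, and 0.252 with an estimated correlation). Acinar genes held 0.157, 2.38 and 0.00753% of the signal in macrophage replicates 1, 2 and 3, and 0.0311, 0.673 and 0.00186% in endothelial replicates 1, 2 and 3, against 0.549 to 1.82% in Dox islets. Of 18 acinar genes 0 passed limma's adjusted test between the fractions; Cpb1 averaged 39847 ± 63764 in macrophages and 13694 ± 22357 in endothelial cells, and Ctrb1 30810 ± 45055 and 6484 ± 10028 (SD, n = 3). With the replicate number as a block, since same-numbered libraries of the fractions deviated together, the adjusted p was 0.00103 for Cpb1 (log2 difference 1.43), 1.03e-05 for Ctrb1 (2.65) and 0.000105 by camera for the acinar list, which without a block had 0.425. The block also moved camera's adjusted p for mural cell genes, lower in macrophages, to 0.00425 from 0.0629 and for the unfolded protein response, higher, to 0.0449 from 0.0647. The adjusted p of the acinar, mural cell and unfolded protein response lists with the block and an estimated correlation was 0.320, 0.302 and 0.372. All values with a block rest on a pairing that the labels do not state. Without replicate 2 of each fraction, the libraries with the most acinar signal, 4990 genes passed between the fractions, 4972 of them among the 8117.

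The comparison of macrophages with whole Dox islets asks which transcripts are enriched by sorting CD11b-positive cells from islets. Among genes chosen on the same terms, Ifnb1, the interferon beta gene, was the most enriched and averaged 2796 ± 820 in macrophages and 1.07 ± 0.129 in Dox islets (SD, n = 3; log2 difference 10.35, SE 0.47, adjusted p = 8.81e-07). Irg1 (8.53), Tnf (8.45), Astl (8.38), Clec4e (8.00), Cxcl2 (7.96), Btnl2 (7.68) and Ccl4 (7.49) followed. The largest depletions were Vip, a neuropeptide gene (-9.48), Kcnj15 (-9.04), Tmem132b (-8.50), Enpp6 (-8.36), Zfp612 (-8.06), Rab3c (-8.02), Sema3g (-7.91) and Nkx6-1, a beta cell transcription factor gene (-7.83). Ifnb1 is ENSMUSG00000048806 on chromosome 4 from 88167929 to 88168698. In all, 7631 of 14479 genes passed limma's adjusted p of 0.05, 3079 higher and 4552 lower in macrophages, and 60.9% of genes had non-overlapping groups, against 10% by chance. The share higher in macrophages, 40.4%, was 52.3% after quantile normalization, in which the median log2 difference of all genes moved from -0.20 to 0.12.

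Against whole islets, macrophage markers, inflammatory genes and genes of the neutrophil and dendritic cell lists were higher. All 17 macrophage markers were higher in the sorted fraction, with C1qa (5.54), Tyrobp (5.43) and Cd14 (5.22) the largest, and 11 of 13 genes of alternatively activated macrophages, with the anti-inflammatory cytokine gene Il10 averaging 7215 ± 1379 in macrophages and 56.7 ± 29.4 in islets (SD, n = 3) and Mgl2 at 5.58; Arg1 (0.81, adjusted p = 0.152) and Lyve1 (-0.70, adjusted p = 0.202) did not pass, though Arg1 was called higher after quantile normalization (1.28, adjusted p = 0.0303). Of the proinflammatory list 12 of 13 were higher, with Tnf, Ccl5 (6.83) and Il12b (6.75) the largest, and Nos2 was lower (-3.73). Of the neutrophil list 8 of 11 were higher, with a median of 5.04, and of the dendritic cell list 7 of 10, with Clec9a (-1.35) and Zbtb46 (-1.01) lower. The chemokine list had 11 of 16 higher, including Cxcl2, Ccl4 and Ccl3 (6.28), and 4 lower. Mmp13 (5.54) was the largest rise among matrix proteases and Timp3 (-5.82) the largest fall, with 7 of 17 higher and 5 lower. All 13 immediate early genes were higher, with the heat shock gene Hspa1a (3.80), Fosb (3.26) and Ier3 (3.12) the largest; Hspa1a has a near copy from which its reads cannot always be told apart. The same counts held adjusted over each list alone, except 8 higher for proteases. Camera's adjusted p was 2.41e-12 for macrophages, 9.55e-06 for alternatively activated, 3.73e-08 for proinflammatory, 6.00e-05 for neutrophils, 0.00245 for dendritic cells, 8.64e-05 for chemokines, 0.182 for proteases and 2.69e-07 for immediate early genes. With an estimated correlation these adjusted p were 0.0806, 0.0806, 0.0806, 0.0806, 0.102, 0.102, 0.410 and 0.102.

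Beta cell, endothelial and basement membrane genes were lower in macrophages than in islets. All 20 beta cell genes were lower (adjusted p = 3.15e-09 by camera, 0.112 with an estimated correlation), with Nkx6-1, G6pc2 (-7.43) and Neurod1 (-7.31) the largest, as were 17 of 18 endothelial markers (1.83e-08 and 0.102), the other being Vwf (-0.65, adjusted p = 0.214), and all 13 basement membrane genes (1.60e-07 and 0.186). Of 18 acinar genes 0 passed limma's adjusted test, though all 18 lay below 0 with a median of -3.09 (adjusted p = 0.193 by camera, 0.762 with an estimated correlation). Without macrophage replicate 2 and Dox islet replicate 1, camera called the acinar list lower (adjusted p = 0.000811). In the list of the other endocrine cells, 6 of 10 were lower and 2 higher. Camera, which compares a list with other genes, did not call it (0.173 and 0.345). By fry, which tests the list by itself, it was called lower (adjusted p = 0.00230). Vegfa was lower (-3.21), Vegfb stood at 0.68 (adjusted p = 0.151; called higher at 1.22, adjusted p = 0.0189, after quantile normalization), and Igf1 averaged 8984 ± 193 in macrophages and 10475 ± 3952 in islets (SD, n = 3; adjusted p = 0.722). Without Dox islet replicate 1, Igf1 was called lower in macrophages (-0.50, adjusted p = 0.00983).

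The comparison of endothelial cells with whole Dox islets asks the same of CD31-positive cells. Endothelial markers were enriched by less than macrophage markers were in their fraction, and beta cell, macrophage and fibroblast genes were strongly depleted. In the endothelial list 17 of 18 were higher, with Icam2 (2.12), Sox18 (1.90) and Tie1 (1.88) the largest, and the other, Erg, averaged 9538 ± 746 in endothelial cells and 14452 ± 9724 in islets (SD, n = 3; adjusted p = 0.789). Without Dox islet replicate 1, Erg was called lower (-1.05, adjusted p = 0.000407), but that fit left the groups in different series of library numbers. In the angiogenesis list 9 of 16 were higher (11 adjusted over the list alone), with the Notch ligand gene Dll4 (1.82), Pdgfb (1.77) and Aplnr the largest, and Esm1 stood at 0.56 (adjusted p = 0.161). Kdr, the gene of VEGF receptor 2, averaged 55024 ± 2777 in endothelial cells and 21280 ± 2802 in islets (SD, n = 3; log2 difference 1.38, SE 0.19, adjusted p = 0.000712), and Vegfa (-5.07), Pgf (-3.97) and Vegfb (-1.28) were lower. In the basement membrane list 5 of 13 were higher, including Hspg2 (2.30) and Lama5 (1.96), Sparc stood at 0.38 (adjusted p = 0.285), and Fn1 was lower (-3.65), with 508 ± 76.4 in endothelial cells and 6499 ± 1605 in islets (SD, n = 3). Camera's adjusted p was 3.76e-08 for endothelial cells, 0.000108 for angiogenesis, 0.255 for VEGF genes and 0.00926 for basement membrane, and 0.153, 0.163, 0.517 and 0.446 with an estimated correlation.

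On the same terms, the largest rises in endothelial cells against islets were in genes outside the endothelial lists. Among them, H1foo averaged 2267 ± 188 in endothelial cells and 283 ± 341 in islets (SD, n = 3; log2 difference 3.73, SE 0.73, adjusted p = 0.00440). Spnb5 (3.57), Sytl1 (3.55), Fut2 (3.47), Apol8 (3.13), Acr (2.96) and Slc16a11 (2.77) followed. The largest falls were Glp1r (-10.08), Resp18 (-9.91), Neurod1 (-9.69), Ucn3 (-9.68), Tmem27 (-9.60), Slc30a8 (-9.58), Nkx6-1 (-9.53) and Scg2 (-9.37). All 20 beta cell genes were lower (camera adjusted p = 3.76e-19, and 0.0317 with an estimated correlation), as were 16 of 17 macrophage markers, with Mpeg1 (-7.13) and Ccr2 (-7.13) the largest and Mertk at 0.28 (adjusted p = 0.274). All 12 fibroblast genes, with Dcn (-6.61) and Lum (-6.58) the largest, and 11 of 12 mural cell genes, with Acta2 (-3.72) and Rgs5 (-3.52), were lower; Cnn1 stood at 0.23 (adjusted p = 0.715) and was called higher after quantile normalization (1.93, adjusted p = 0.0116). All 18 acinar genes lay below 0, with a median of -4.75. Of these, 2 were lower and 16 did not pass limma's adjusted test, while 16 were lower adjusted over the list alone (camera adjusted p = 0.00402, and 0.539 with an estimated correlation). Of the immediate early list 5 of 13 were higher, namely Nr4a1 (2.16), Hspa1a (1.98), Ier3, Dusp1 (0.95) and Jun (0.76), and Egr1 stood at 0.29 (adjusted p = 0.327). For macrophages, fibroblasts, mural cells and immediate early genes camera's adjusted p was 2.93e-08, 2.93e-08, 0.000146 and 0.00351, and 0.163, 0.252, 0.334 and 0.254 with an estimated correlation. In all, 4706 of 14218 genes passed limma's adjusted p of 0.05, 1635 higher and 3071 lower, and 48.3% had non-overlapping groups, against 10% by chance. The count was 7156 without Dox islet replicate 1, 2994 without Dox islet replicate 2 and 2301 without Dox islet replicate 3. All endothelial libraries had library numbers of series 35, and Dox islet replicates 1, 2 and 3 of series 35, 36 and 36. Cell type and series were thus partly confounded, and fully so without Dox islet replicate 1. No series covariate was fitted in this comparison. The share higher, 34.7%, was 58.4% after quantile normalization, in which the median log2 difference of all genes was 0.29 instead of 0.00.

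**Figure D3:**
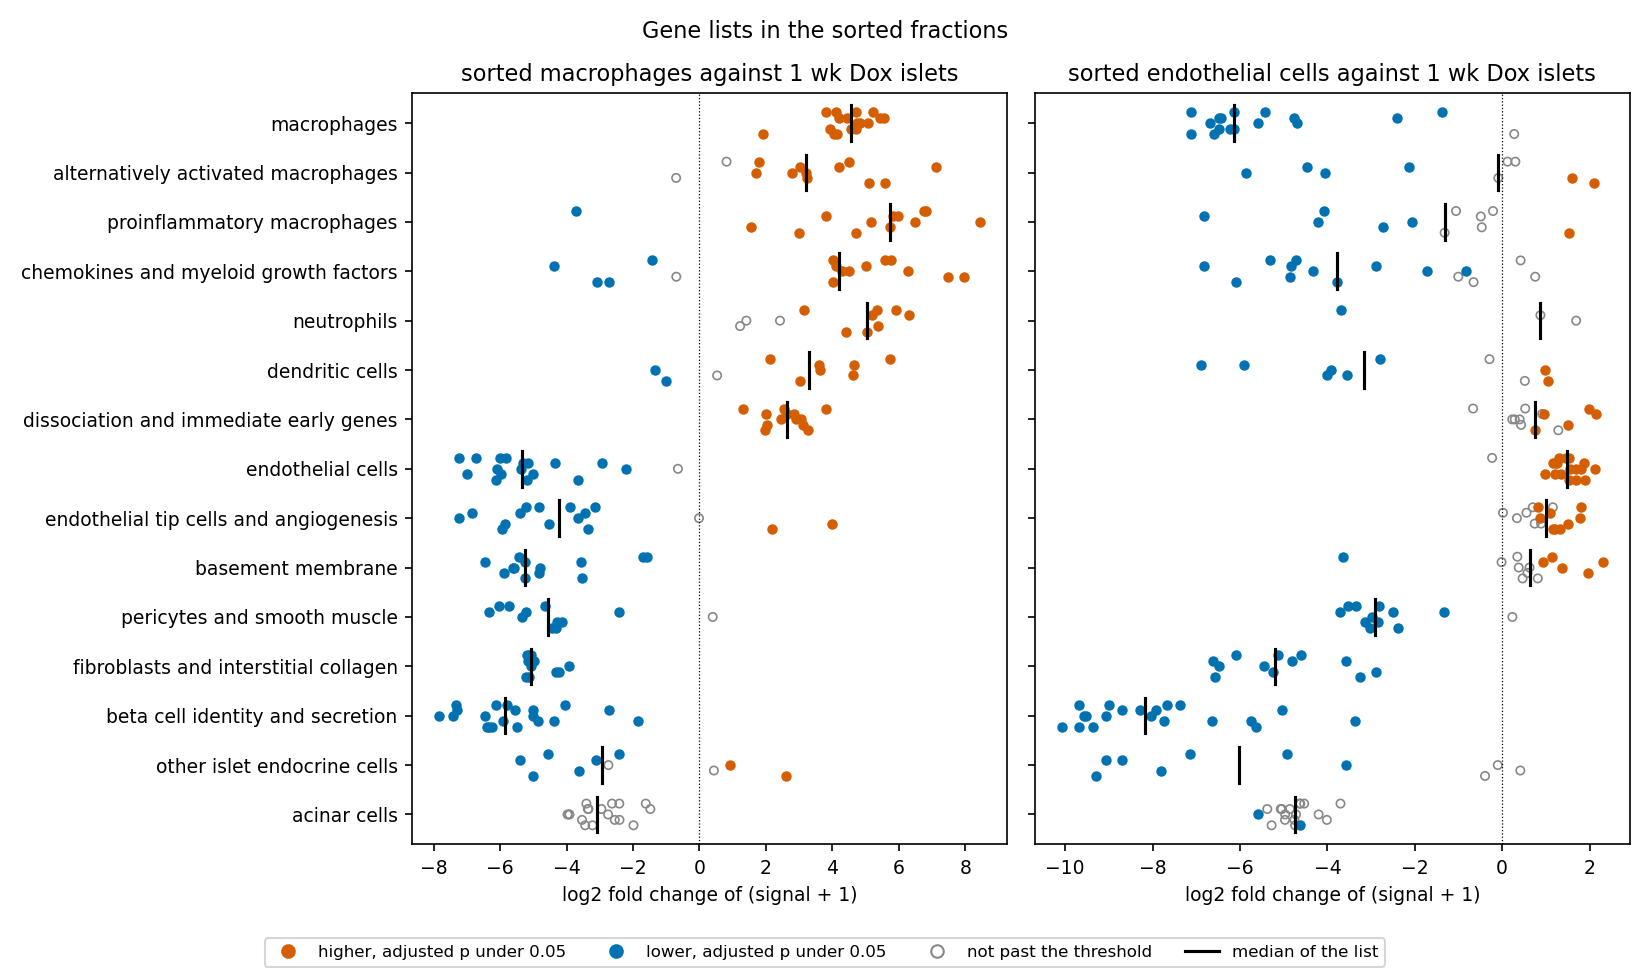
Log2 fold change of (signal + 1) of each tested member of 15 gene lists in sorted macrophages (left) and sorted endothelial cells (right), each against whole Dox islets (3 against 3 libraries); vertical lines are list medians, filled points passed limma's adjusted p of 0.05 and open points did not. The median was 4.57 for macrophage markers in macrophages and 1.49 for endothelial markers in endothelial cells, and -5.86 and -8.17 for beta cell genes; the horizontal scales of the panels differ.

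Genes higher in sorted endothelial cells than in sorted macrophages rose in Dox islets more often than genes higher in macrophages did. Of 4251 genes higher in endothelial cells, 380 (8.94%) rose in Dox islets, and of 3475 genes higher in macrophages, 116 (3.34%) did, an odds ratio of 2.84 (95% interval 2.29 to 3.55) with p = 8.52e-25 in a two-sided Fisher's exact test over genes tested in both comparisons. Without Dox islet replicate 2, which left 5 changed genes in islets, the odds ratio was 1.63 (p = 1 by Fisher's exact test), and without Dox islet replicate 3 it was 9.37. A further 112 of the 608 risen genes differed between the fractions in neither direction. Of 139 genes that fell, 75 were higher in macrophages and 16 in endothelial cells. A gene higher in one fraction need not be expressed by its cells, since both carried transcripts of other cells. Of the 380, 180 were called higher and 54 lower in endothelial cells than in Dox islets, and 6 of the 75 were on the beta cell list. The comparisons shared no library, and genes are not independent replicates, so this p describes these libraries. The odds ratio counts genes past the threshold and not the size of their change. In islets the median log2 change was 1.65 for the macrophage list and 1.42 for the endothelial list. It therefore does not rank the cell types by their response.

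**Figure D4:**
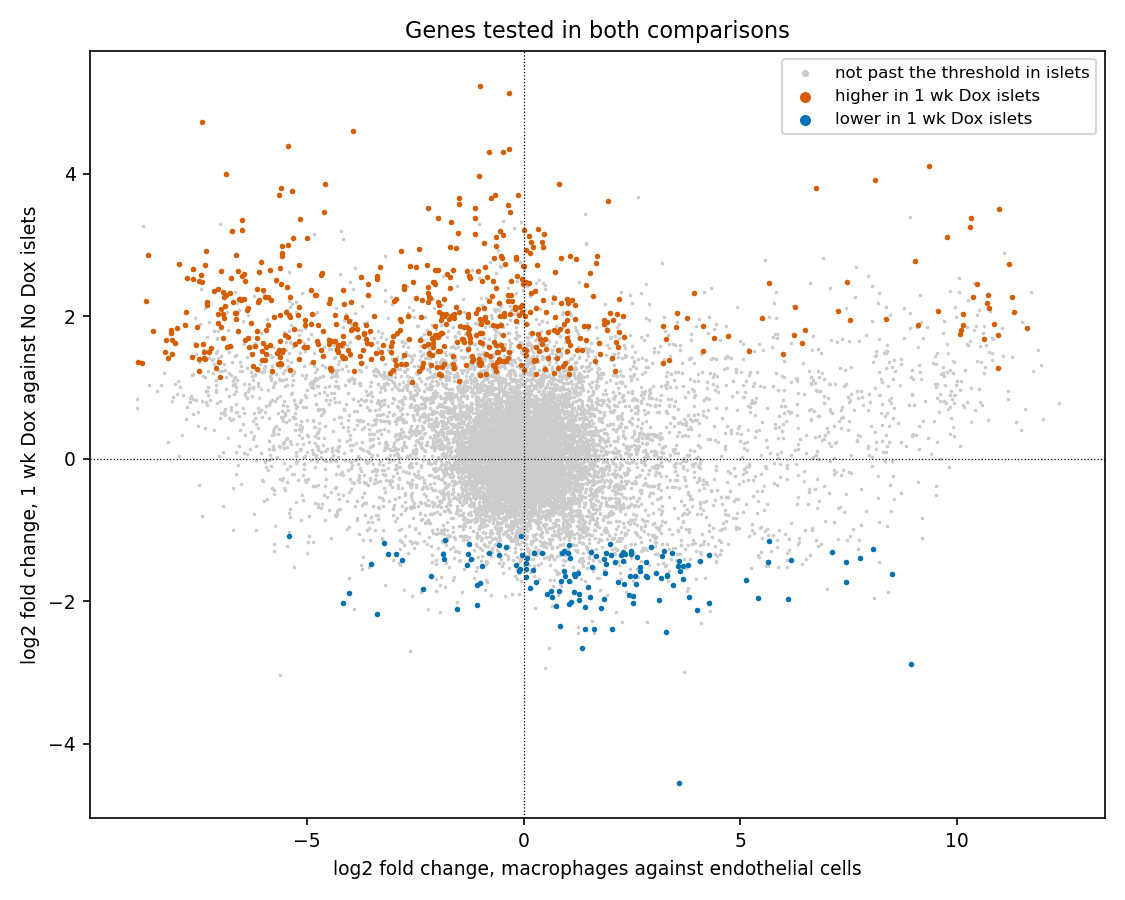
Each point is a gene tested in both comparisons (13173 genes), with its log2 fold change between sorted macrophages and endothelial cells on the horizontal axis (positive, higher in macrophages) and between Dox and No Dox islets on the vertical axis; coloured points passed limma's adjusted p of 0.05 in islets. Of the 608 risen genes, 380 were called higher in endothelial cells and 116 in macrophages.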

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

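Directions held for all 202 called named genes in each alternative in which they were tested, but calls did not hold alike. As these genes had passed, and the largest rises and falls were chosen for no overlap of groups, a change of sign was unlikely from the start. The filter removed some genes in fits with fewer libraries, so only 60 of 62 called named genes in islets, 36 of 56 between the fractions, 25 of 37 in macrophages against islets and 42 of 47 in endothelial cells against islets were tested in every alternative. Of these, 4, 35, 25 and 19 passed in all of them. The GC trend, the 2 libraries left out, the covariate for the library number series, the estimated correlation with a replicate block and the odds ratio with 1 library left out were chosen after seeing the data. The odds ratio of the islet response ran from 2.52 to 4.04 over the other alternatives and from 1.63 (without Dox replicate 2, p = 1 by Fisher's exact test) to 9.37 (without Dox replicate 3) leaving out 1 library, and the beta cell background within its spread. Of genes changed in islets, 829 became 97 with no filter, 1606 with the 4 groups in one fit, 301 with no variance trend, 1679 with the GC trend removed, 301 with the 2 libraries that stand apart left out, and 524 with the library number series as a covariate. Leaving out 1 library gave 5 (without Dox replicate 2) to 801 (without No Dox replicate 2), with 88 without Dox replicate 3 and 456 without No Dox replicate 1. Between the fractions, 4990 genes passed without the 2 libraries apart, and in endothelial cells against islets 2301 (without Dox islet replicate 3) to 7156 (without Dox islet replicate 1). Fewer libraries explain part of the smaller counts by construction; otherwise the cause was not tested. With an estimated correlation 0, 0, 0 and 1 lists were called, against 21, 14, 17 and 15, in the order of the report (0 between the fractions with a replicate block as well), and fry called 26 between the fractions.

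With a replicate block, 679 genes passed in islets, 8676 between the fractions, 8070 in macrophages against islets and 5193 in endothelial cells against islets, and 20, 17, 17 and 15 lists. By the check of same-numbered deviations only the fractions looked paired, which 3 libraries per group cannot establish. In islets these deviations correlated at -0.25, -0.52 and 0.17 (0 of 6 libraries closest to their number). They correlated at 0.20, 0.03 and 0.03 in macrophages and islets (2 of 6). In endothelial cells and islets the values were 0.26, -0.01 and 0.05 (2 of 6). Between the fractions the block changed the calls of Arg1, Cpb1 and Ctrb1 and of 3 lists, given in the report, and no other call of a named gene or list.

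Some values that had not passed changed sign; the cause was not tested. In islets, Fos stood at -0.19 after quantile normalization, -0.071 after median ratio rescaling and -0.082 with the GC trend removed, and Csf3r at -0.076 without the 2 libraries apart. Leaving out 1 library gave ranges of -0.61 to 0.39 for Ccng1, -0.042 to 1.13 for Cd86, -0.97 to 0.17 for Cdh19, -0.21 to 1.06 for Elane, -0.27 to 0.29 for Fos, -0.91 to 0.50 for Hbb-b1, -1.40 to 0.11 for Hbb-b2, -0.90 to 0.020 for Hsp90b1 and -0.068 to 0.90 for Il1b. Between the fractions, Igf1 stood at 0.038 after quantile normalization, 0.066 after median ratio rescaling, 0.24 with the GC trend removed (0.24 also with a replicate block) and 0.049 without the 2 libraries apart; leaving out 1 library gave -0.15 to 0.063 for Igf1 and -0.93 to 4.04 for Cpb1. In macrophages against islets, Igf1 stood at 0.079 after median ratio rescaling and 0.47 with the GC trend removed, and from -0.50 to 0.082 leaving out 1 library; Erg in endothelial cells against islets ran from -1.05 to 0.27.

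Other genes that had not passed were called under an alternative. In islets, besides Vegfa, these were Lyz2, Zbtb46, Cd4, Cd81, Clec9a, Itga1, Mbp, Mki67, Nrp1, Ptprb, Timp3, Trp53i11, Gcg, Iapp, Rgs5, Ttr, Ctrb1, Trac and Hspg2, and of lists, p53 and apoptosis was called by fry and 4 other alternatives (lowest adjusted p = 0.0147), hypoxia by fry (0.0252) and the other endocrine cells after quantile normalization (0.0386). In endothelial cells against islets, Esm1 was called with the GC trend removed (0.76, adjusted p = 0.00758) and Sparc without the 2 libraries apart (0.57, adjusted p = 0.0478). Without the 2 libraries apart, Erg there (0.00207) and Igf1 in macrophages against islets (0.0369) were called lower. Leaving them out also put endothelial cells and islets in different series of library numbers. Between the fractions, with no filter, camera also called mural cells (adjusted p = 0.0243), the unfolded protein response (0.0260), matrix proteases (0.0296), growth factors (0.0354) and T, NK and B cells (0.0485).

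Lists whose direction changed had these adjusted p there. In islets, neutrophils had 0.878 by fry, 0.980 after quantile normalization, 0.996 after median ratio rescaling and 0.961 with the GC trend removed, red blood cells 0.906 by fry, and ductal and Schwann cells 0.986 and 0.917 without the 2 libraries apart. Dendritic cells between the fractions had 0.979 without them. In macrophages against islets, beta cell immaturity had 0.00622 by fry and 0.881 with the GC trend removed, and red blood cells 0.960 without the 2 libraries apart. In endothelial cells against islets, neutrophils had 0.774 by fry, 0.259 with no filter and 0.977 with a filter of 5; without the 2 libraries apart, beta cell immaturity had 0.759, dendritic cells 0.160 and integrins 0.780. Depth cannot be stated without read numbers, and 3 libraries per group limit what the test can find.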

Other observations

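Genes of the interferon response were higher in sorted macrophages. Against endothelial cells 11 of 14 were higher and 1 lower (the same adjusted over the list alone), and against islets 10 of 14 (11 adjusted over the list alone) with 1 lower. Mx1, an antiviral GTPase, averaged 2987 ± 687 in macrophages, 29.6 ± 11.4 in endothelial cells and 90.1 ± 21.9 in Dox islets (SD, n = 3), and Isg15, a ubiquitin-like modifier, 742 ± 71.7, 99.8 ± 18.9 and 28.3 ± 32.4 (SD, n = 3). By camera the adjusted p was 0.00125 and 8.25e-05, and with an estimated correlation 0.302 and 0.167.

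Several genes on the myeloid lists were higher in endothelial cells than in Dox islets. Il10 (2.11), the scavenger receptor gene Stab1 (1.60), Nos2 (1.52), Zbtb46 (1.05) and Clec9a (0.99) passed limma's adjusted test, and the last 3 were lower in macrophages than in islets, with Nos2 at -3.73, Clec9a at -1.35 and Zbtb46 at -1.01. These names were singled out after their values were seen. In the cell cycle list 5 of 20 genes were higher in endothelial cells than in islets (0 adjusted over the list alone), including Birc5 (1.39), Mcm3 (1.21) and Cdk1 (1.17). Mki67 averaged 12681 ± 721 in endothelial cells and 9826 ± 6418 in islets (SD, n = 3; adjusted p = 0.316) and was called higher without Dox islet replicate 2 (1.08, adjusted p = 0.0259). Camera's adjusted p for the list was 0.000605, and 0.446 with an estimated correlation.

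The tests of the 3 patterns that follow were chosen after the results were seen; the counts over other splits of the libraries were set before. Beta cell genes were lower in Dox islets, with a list median of -1.58. A lower share of beta cells with no other change would move the markers of the other cell types alike. The 10 marker lists compared differed (permutation p = 1e-04, the smallest 10000 permutations can give). As vessel and macrophage genes rose with Dox, these lists could differ whatever the share of beta cells. That test therefore cannot tell whether a lower share accounts for the fall of beta cell genes. Dilution of all endocrine cells would lower the other endocrine genes as far, but their median was -0.79 (permutation p = 4e-05). Genes are not independent replicates. With the GC trend removed, the median of the beta cell list was -1.71 (camera adjusted p = 2.94e-14, over all alternatives 4.25e-19 to 0.0694, the highest with an estimated correlation), which argues against that trend as the whole cause. Lower expression per beta cell may contribute, a hypothesis that whole islet RNA leaves untested, as it does a combination of fewer beta cells with other changes.

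Inflammatory genes were high in sorted macrophages against Dox islets. Purification alone would enrich them about as much as macrophage markers, but the proinflammatory list had a median of 5.75 against 4.57 (permutation p = 0.00727), and 7 of 13 members, with 5 of 16 chemokine genes, lay above the highest marker, at 5.54. Transcripts made during dispersal and sorting are a candidate explanation: immediate early genes were also higher in sorted endothelial cells than in islets, with a median of 0.762 (camera adjusted p = 0.00351, and 0.254 with an estimated correlation). As each sorted library was dispersed and no whole islet library was, this cannot be told apart from a difference between macrophage states. Other CD11b-positive cells in the fraction were not tested as an explanation; the highest neutrophil and dendritic cell genes, at 6.31 and 5.73, also lay above the highest marker.

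Among islets, No Dox replicate 2 and Dox replicate 1 deviated together from their group means, with a correlation over 14423 genes of 0.780. GC-dependent yield would account for it if removing the GC trend ended it, but the correlation stayed at 0.662, and with a length trend removed it was 0.775. Neither trend is therefore the whole cause, though GC may account for a part. No biological explanation was tested, since the labels give none for these 2 libraries.

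For each comparison, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In every comparison 1 split, the real one, gave as many genes, with 829, 8117, 7631 and 4706, and the highest of the others gave 0. As many lists as the real split (21, 14, 17 and 15) came from 1, 5, 4 and 1 of the 10 splits, and the highest others gave 20, 17, 18 and 13. Between the fractions, the other splits that part all same-numbered libraries gave 0 genes and 11, 11 and 14 lists.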
